A study of Mus musculus with 2 samples.

How the data were processed

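RNA-seq was made from the whole body and the telencephalon of wild-type ICR mouse fetuses at E12.5, per the labels' protocols. Total RNA was extracted with a column kit, libraries were prepared with a TruSeq RNA v2 kit, which selects polyadenylated RNA and does not mark strand, and sequencing was on a HiSeq 2000. Each group has 1 library. The labels do not say how many fetuses went into a library, what sex they were, or whether the whole body included the head.

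The values are FPKM per gene and FPKM per isoform, as the authors deposited them, in 2 tables with a column for each library. TopHat, Cufflinks and Cuffdiff were used with the GRCm38 genome, per the submitters' processing notes, which give no versions. The release of the annotation is not given in the sources used here. FPKM values are relative to the transcript length and to the mapped fragments of the library, so they are not counts, and a model for counts was not run. The columns summed to 502131 FPKM in whole body and 447888 in telencephalon. The 10 most abundant genes took 19.7% and 14.2% of these sums, and small RNA genes 15.9% and 8.70%. The 43437 genes were matched on the Ensembl gene identifier without its version to the GENCODE M21 annotation, which is of the same build. There were 42276 matches, and 126 of the 14987 measured genes had none. Coordinates, biotypes and transcript lengths come from that annotation. For a symbol on several rows, the row with the higher summed FPKM was used in lists.

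Depth was taken from the low values. In genes with a single isoform the FPKM of 1 fragment falls with transcript length. A fit of the lowest steps over 407 genes in whole body and 455 in telencephalon gave 29400000 and 22800000 fragments, with 323 and 337 bases subtracted from each transcript's length, a relative depth of 1.29. Among single-isoform genes of 2000 bases or more, 93.0% of 1181 values and 90.9% of 1401 values came out whole within 0.1 fragments. Chance gives 20%, but genes of the fit are included. Those come out near 1 fragment by the way they were kept, so the check is partly circular. At 2000 bases, 3 fragments correspond to 0.0609 and 0.0792 FPKM. Fragment numbers in the text are such estimates and carry counting error only, since the libraries have no molecular identifiers. Transcripts shorter than the fragments receive a large length correction, and genes whose signal comes from isoforms under 300 bases are named as such.

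For each gene the log2 ratio of telencephalon to whole body was taken after adding a pseudocount of 1 FPKM. A gene was measured if it had 1 FPKM or more in either library. Genes past 2-fold were counted by direction, and counts at 4-fold and 8-fold are given as description. With 1 library per group there is no replicate error, and no test or p-value was computed. Long non-coding RNA genes were those of the annotation's long non-coding biotypes, including processed transcripts.

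Before the data were examined, 23 gene lists, the design, the alternatives and the rule for named genes were fixed. Each list's median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins, and the percentile describes these libraries. Of 492 list symbols 11 are not analysed here. The rule for named genes took the 12 largest and 12 smallest log2 ratios among genes of 5 FPKM or more in either library, without symbols of small RNAs and mitochondrial genes, of the model forms Gm, AC, AL or CT with a number, ending in Rik, or ending in -ps with a number. Clone names beginning with RP are not among these forms, and 4 of the 24 genes have such names. It took from each list the 2 measured members farthest in the direction of the median and the 1 farthest the other way. It also took the 6 largest and 6 smallest long non-coding RNAs, Redrum, and the 6 genes with the largest difference in an isoform's share. A symbol on several rows was named only if its rows agreed in direction. Some genes that the rule selects are not reported here. Other members of lists that appear in the text as examples, the gene families and the example pairs of neighbouring genes were chosen after their values were seen.

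The isoform comparison took genes with at least 2 isoforms and summed isoform FPKM of 5 or more in both libraries. For Redrum the interval of the ratio is the exact 95% binomial interval of the 2 fragment estimates, scaled by depth. Globin transcripts were compared with all annotated transcripts in stretches of 50 bases. Long non-coding RNA genes were paired with the nearest measured protein-coding gene, leaving out genes with 10% or more of their signal in isoforms under 300 bases, and Spearman's rho was set against 10000 random re-pairings.

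The counting of differences was tested on simulated values of 12955 genes with known changes. Only counting noise was simulated, so variation between libraries and the division of reads among isoforms were not covered. At a log2 change of 1.5, 2, 3 or 4, 50 genes each, 100% passed the 2-fold threshold, and 0% of 12755 unchanged genes did. Genes with only short transcripts and genes with a mean below 1 FPKM were left out of the 12955. These rates therefore do not cover such genes, some of which are among the 14987 measured genes. In the list step 4 of 100 unchanged lists of 20 genes lay outside the central 95%, and a list raised by 2 on the log2 scale lay at percentile 100. The isoform step, run on 6741 genes, found 200 of 200 swapped genes. It compared the telencephalon values with a copy of themselves without noise, so it checks the code and not the error of the shares.

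Alternatives were pseudocounts of 0.1 and 5 FPKM, no floor and a floor of 5 FPKM, 4 other scalings, gene values summed from isoforms, other floors for isoforms, and a leading share of 60% or more. The scalings were TPM, TPM without globin, mitochondrial and small RNA genes, a median ratio of 0, and a common upper quartile. Gene values from isoforms of 300 bases or more were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.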

Results

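Polyadenylated RNA was sequenced from the whole body and from the telencephalon of wild-type ICR mouse fetuses at E12.5, with 1 library for each. ICR is an outbred mouse stock, and the telencephalon is the front part of the embryonic brain, from which the cerebral cortex and the basal ganglia develop. The 2 tables gave FPKM, the number of fragments scaled by transcript length and by the mapped fragments of the library, for 43437 genes and 103615 isoforms. The FPKM steps of single-isoform genes corresponded to about 29400000 fragments in the whole-body library and 22800000 in the telencephalon library. A single fragment on a transcript of 2000 bases was therefore worth 0.0203 and 0.0264 FPKM. Genes above 0 numbered 23016 in whole body and 21998 in telencephalon, and genes of 1 FPKM or more 14343 and 12778. The comparison asks which genes, and above all which long non-coding RNAs, differ between the telencephalon and the body as a whole. With 1 library per group none of the differences has a replicate check, so no p-value is given and each value describes these 2 libraries. Differences are log2 ratios of FPKM + 1 (telencephalon over whole body), which understate the difference for weakly expressed genes, and folds are ratios of FPKM.

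The telencephalon library held higher levels of forebrain patterning genes, while genes of liver, muscle, skeleton and blood were lower in it, some by more than 100-fold. Dlx2, a homeobox gene of the ganglionic eminences in the ventral telencephalon (chromosome 2, 71543408 to 71546754), stood at 212 FPKM in telencephalon and 5.40 in whole body. Afp, the fetal serum protein made in liver and yolk sac (chromosome 5, 90490737 to 90508907), stood at 1.03 and 843 FPKM. Of 14987 genes with 1 FPKM or more in either library, 1408 were at least 2-fold higher in telencephalon, 3170 at least 2-fold lower, and 10409 lay within 2-fold. At 4-fold the counts were 329 higher and 1234 lower, and at 8-fold 98 and 505. Among 13706 protein-coding genes, 1152 were higher and 2939 lower. The median log2 ratio of all measured genes was -0.16, and scaling to a common upper quartile moved it to 0.04, while rescaling to TPM moved it to -0.02. Across the 12134 genes of 1 FPKM or more in both libraries, Pearson's r of log2(FPKM + 1) was 0.816 and Spearman's rho 0.801. Genes below 1 FPKM in 1 of the libraries were left out of these coefficients. These run across genes, which are not independent replicates.

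**Figure D1:**
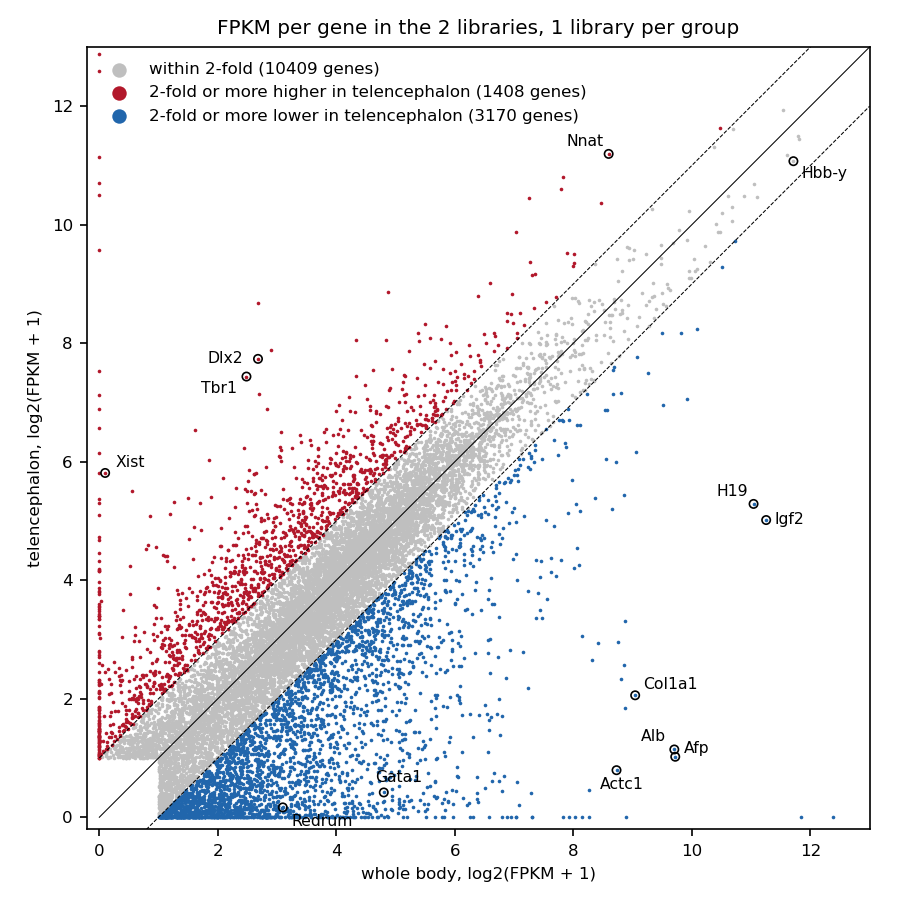
Each point is a gene with 1 FPKM or more in either library, with log2(FPKM + 1) in whole body on the x axis and in telencephalon on the y axis, 1 library each. The solid line marks equal values and the dashed lines a 2-fold difference, and 1408 genes lie above and 3170 below the dashed band, with Dlx2 and Tbr1 at the upper left and Afp, Alb and Actc1 at the lower right.

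Genes of both the dorsal and the ventral telencephalon were higher in the telencephalon library. Of 19 measured pallial genes, which mark the dorsal part that becomes cortex, 16 were at least 2-fold higher and none lower (median log2 ratio 2.09). Tbr1, a transcription factor of early cortical neurons, was 37.5-fold higher (172 against 4.59 FPKM), and Fezf1 18.7-fold. Eomes, a marker of intermediate progenitors, stood at 24.8 against 1.86 FPKM. Of 20 subpallial and GABA-lineage genes 18 were higher and none lower (median 3.61), the largest median among the 23 lists. Dlx2 was 39.3-fold higher and Lhx6, a gene of migrating interneurons, stood at 118 against 6.09 FPKM. The GABA-synthesising enzymes Gad1 and Gad2 stood at 32.1 and 38.4 FPKM against 3.56 and 2.24. Of 13 measured pan-telencephalic and anterior forebrain transcription factors 10 were higher and none lower (median 2.07), including Sox2 (9.81-fold), while Zic1 was 31.8 against 31.4 FPKM. All of these medians lay at percentile 100 of the medians of 10000 random lists of the same size matched on expression.

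Neural progenitor and neuronal genes were also higher in telencephalon, with exceptions. Of 20 radial glia genes 13 were at least 2-fold higher and 3 lower (median 1.62, percentile 100). Sox1, a transcription factor of the early neural plate and neural progenitors, was 22.2-fold higher, and Hes5, a target of Notch signalling, 12.2-fold. Gas1, a membrane protein that binds hedgehog ligands, was 6.30-fold lower (15.4 against 97.1 FPKM), and Hes1 and Mfge8 were the other lower members. Of 19 genes of differentiating neurons 16 were higher and 2 lower (median 1.70, percentile 100). Elavl3 was 6.08-fold higher and Map2 5.53-fold, whereas the neurofilament genes Nefl (16 against 47.6 FPKM) and Nefm (21.4 against 44.0) were lower. The 10 genes of Cajal-Retzius cells, the earliest neurons at the cortical surface, split evenly, with 3 higher, 3 lower and a median of -0.02 at percentile 75.4 that turned positive with a common upper quartile (0.14) and in TPM (0.12). Trp73 was 11.4-fold higher, Ebf3 7.19-fold lower and Ebf2 4.74-fold lower, and Reln stood at 16.7 against 14.9 FPKM.

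Genes of the rest of the nervous system and of the trunk axis were lower in telencephalon. Of 33 measured Hox genes, which set position along the body from the hindbrain to the tail, 31 were at least 2-fold lower and none higher (median -2.46, percentile 0). Hoxb8 was 68.3-fold lower (0.673 against 46.0 FPKM) and Hoxb9 164-fold, on about 6 fragments in telencephalon. Of 18 genes of hindbrain, spinal cord and peripheral nervous system 14 were lower and 1 higher (median -2.03, percentile 0). Prph, an intermediate filament of peripheral neurons, was 49.7-fold lower. The exception was the vesicular glutamate transporter gene Slc17a6 (11.9 against 4.69 FPKM). Of 15 genes of diencephalon, eye and choroid plexus 9 were lower and 2 higher (median -1.14, percentile 1.83). The lens gene Cryaa stood at 0.103 against 33.7 FPKM, the former from about 2 fragments. Ttr, which choroid plexus and liver express, was 44.5-fold lower, whereas Vax1, a homeobox gene of the ventral forebrain, was 14.2-fold higher (7.38 against 0.519 FPKM).

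Genes of liver, connective tissue, muscle and epithelia were lower in telencephalon, some by more than 100-fold. Of 24 hepatoblast genes 23 were at least 2-fold lower (median -4.62), and Alb, the serum albumin gene, was 689-fold lower (1.21 against 833 FPKM, about 47 against 41886 fragments). Of 25 cartilage, bone and connective tissue genes 24 were lower (median -4.90), among them the type I collagen genes Col1a2 (183-fold) and Col1a1 (167-fold). Sox9, which neural progenitors also express, was 21.5 against 25.6 FPKM. All 19 cardiac muscle genes (median -2.80) and all 18 skeletal muscle genes (median -3.09) were lower. The cardiac actin gene Actc1 was 577-fold lower, and the skeletal myosin light chain gene Mylpf 219-fold on about 4 fragments. The troponin genes Tnni1 and Tnnc1 stood at 61.4 and 74.7 FPKM in whole body and had about 1 fragment each in telencephalon. All 18 epithelial genes were lower (median -3.05), with Krt5, a keratin of basal skin cells, 288-fold lower on about 4 fragments. Krt14 was listed at 0 in telencephalon and at 21.5 FPKM in whole body. The median of each of these lists lay at percentile 0.

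Genes of cells that enter or surround the brain were lower too. Of 20 endothelial genes 17 were at least 2-fold lower and none higher (median -1.49, percentile 0). Emcn was 8.27-fold lower and Icam2 7.27-fold, while Cldn5, a tight-junction gene of brain endothelium, was 24.4 against 27.2 FPKM. Of 18 macrophage and microglia genes 16 were lower (median -1.83, percentile 0.02). Pf4 was 21.7-fold lower and Lyz2 38.6-fold, and Cx3cr1, a chemokine receptor of microglia, stood at 3.32 against 8.30 FPKM. Of 17 genes of meninges and perivascular mesenchyme 11 were lower and none higher (median -2.56, percentile 0). Islr was 35.9-fold lower, and Aldh1a2, an enzyme that makes retinoic acid, stood at 0.0456 against 21.6 FPKM, the former from about 2 fragments.

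Erythroid genes were lower in telencephalon, although the embryonic globins differed less than the rest except Bpgm. Of 27 measured erythroid genes 23 were at least 2-fold lower and none higher (median -3.87, percentile 0). Rhd, a membrane protein of red cells, was 137-fold lower and the anion exchanger gene Slc4a1 59.7-fold lower (5.32 against 318 FPKM). Gata1, the transcription factor that directs erythroid differentiation, stood at 0.337 against 26.9 FPKM. The 3 embryonic globin genes kept 53.3% to 68.1% of their whole-body FPKM in telencephalon. Hbb-y had 2153 against 3360 FPKM and Hba-x 438 against 643. The 4 other globin genes had 8.86% to 22.7% of the whole-body value, but only 13.1% to 41.7% of the 50-base stretches of their transcripts occur in no other gene, so their single values are uncertain. The 20 erythroid genes other than globins had a median of 2.29%, with Bpgm the highest at 96.1%.

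**Figure D2:**
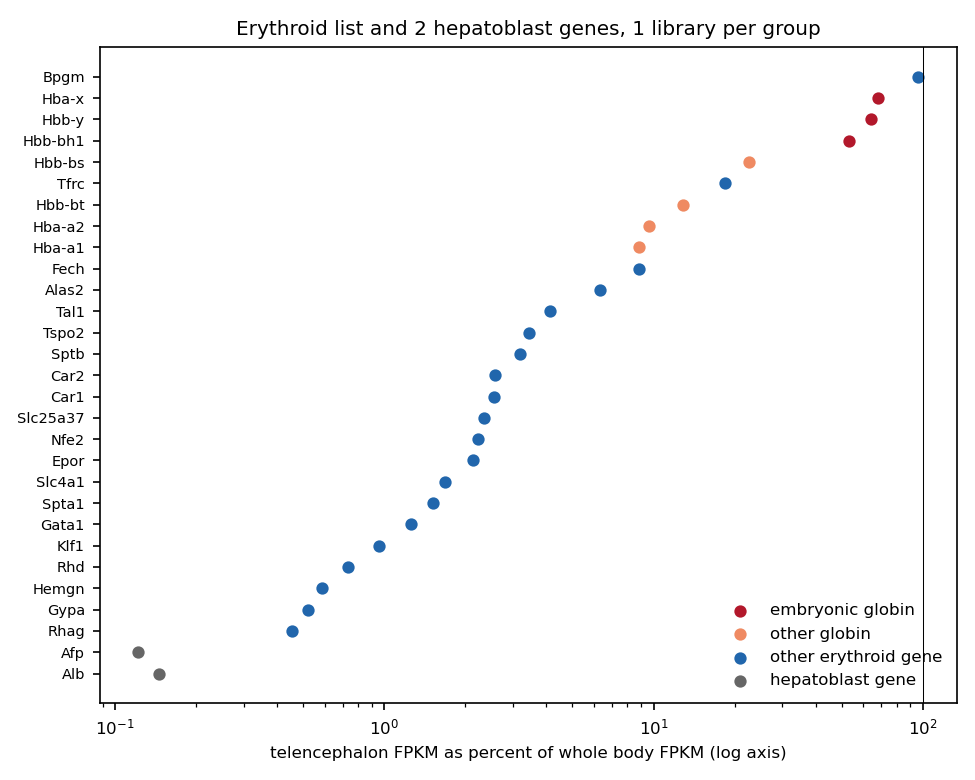
Telencephalon FPKM is drawn as a percent of whole-body FPKM on a logarithmic axis for the 27 measured erythroid genes and for the hepatoblast genes Alb and Afp, with 1 library per group and the vertical line at equal values. The 3 embryonic globin genes lie between 53.3% and 68.1%, Gata1 at 1.25% and Alb at 0.145%.

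Imprinted genes split into a group with far lower and a group with higher levels in telencephalon, and cell cycle genes lay within 2-fold. Of 29 imprinted genes 17 were at least 2-fold lower and 6 higher (median -1.37, percentile 0). The fetal growth factor gene Igf2 was 77.9-fold lower (31.4 against 2442 FPKM) and its neighbour H19, a long non-coding RNA, 55.4-fold lower (38.1 against 2107). Nnat, a small membrane protein of developing brain, was 6.07-fold higher (2344 against 386 FPKM), and Ndn (363 against 116) and Snrpn (127 against 34.8) were higher as well. None of 22 cell cycle genes differed by 2-fold (median -0.35, percentile 0.46). Mki67, a nuclear protein of dividing cells, stood at 27.3 against 54.5 FPKM, Birc5 at 36.0 against 68.8 and Top2a at 87.6 against 80.6.

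The 15 housekeeping genes had a median of -0.66 (percentile 0.15), and 5 were at least 2-fold lower. B2m, the light chain of major histocompatibility class I, was 10.2-fold lower, while Tbp was 31.1 against 20.4 FPKM. The median stayed below 0 under each scaling tried. The 4 Y-linked genes were lower in telencephalon and Xist, the RNA that coats the inactive X chromosome of females, was higher (list median -1.15, mean -0.07, percentile 4.43). Ddx3y was 5.56-fold lower (1.96 against 10.9 FPKM), Eif2s3y 3.86-fold, and Xist stood at 55.1 against 0.0703 FPKM. The labels give neither the sex nor the number of the fetuses.

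**Figure D3:**
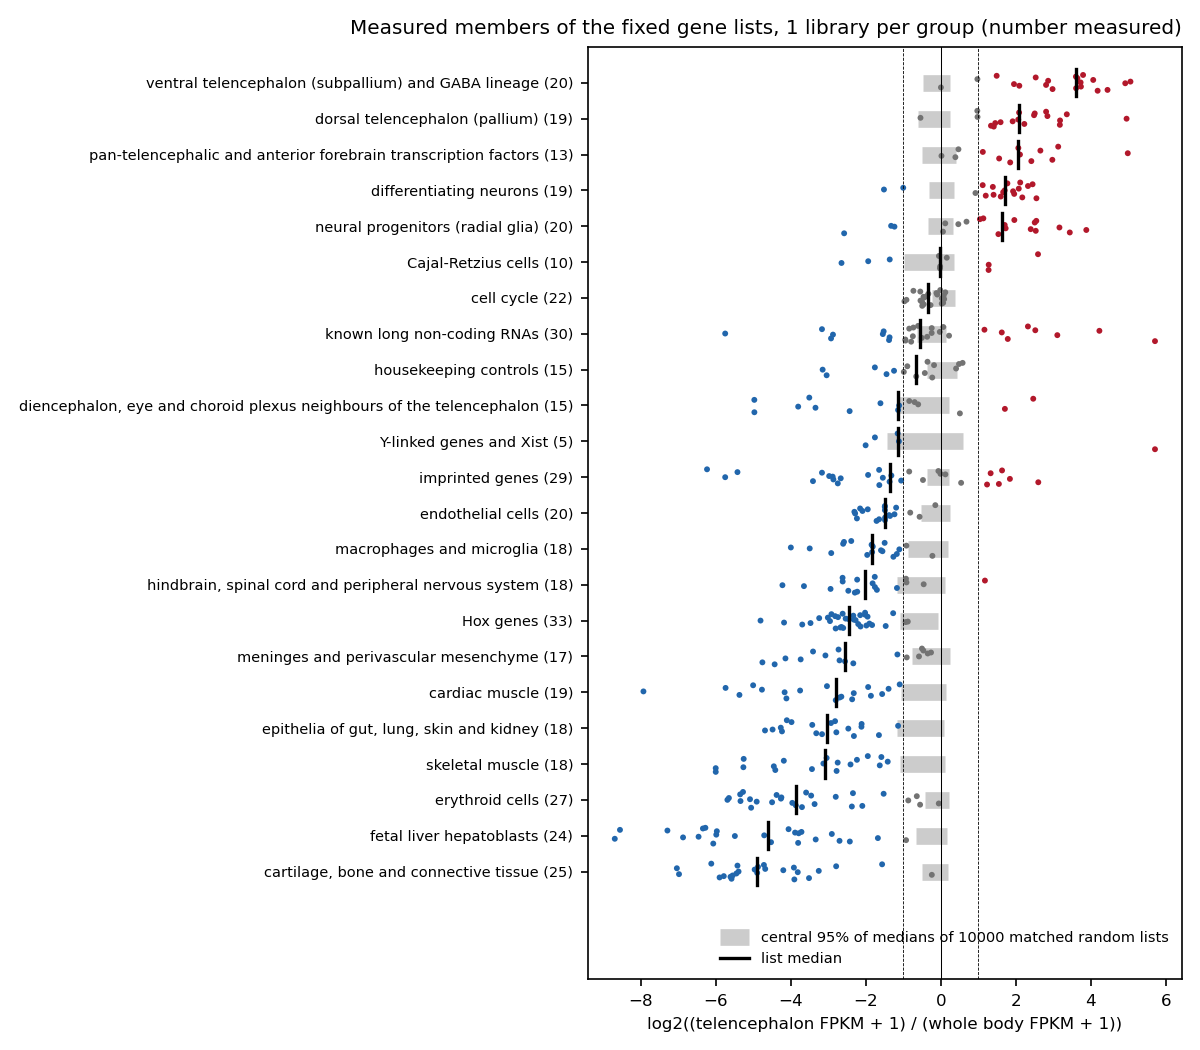
Each point is a measured gene of a fixed list, placed on the x axis by its log2 ratio of FPKM + 1 (telencephalon over whole body, 1 library each), with 2-fold higher genes in red and 2-fold lower genes in blue. Black bars mark list medians and grey bands the central 95% of medians of 10000 matched random lists, and the medians run from -4.90 for cartilage, bone and connective tissue to 3.61 for subpallium and GABA lineage.

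The 24 genes with the most extreme ratios among those of 5 FPKM or more included forebrain, liver, muscle and collagen genes. Besides Xist, Dlx2 and Tbr1, the higher end included Dlx1 (25.6-fold), the ventral forebrain gene Nkx2-1 (24.8-fold), the Dlx6 antisense RNA Dlx6os1 (40.8-fold) and Clvs2, a lipid-binding protein of neurons (95.9-fold), 97.0% of it in telencephalon from a non-coding isoform of 1027 bases. In whole body a 2717-base isoform held 91.6% of Clvs2, so its fold depends on how reads were divided among isoforms. Clvs2 had about 33 fragments in whole body and 749 in telencephalon. The lower end included Afp, Alb, Actc1, Col1a2 and Col1a1. It also held Serpina6 (810-fold), which encodes the corticosteroid carrier of serum, the retinol carrier gene Rbp4 (0.148 against 134 FPKM, about 2 fragments in telencephalon) and the smooth muscle actin gene Acta2 (462-fold). The apolipoprotein gene Apoa2 was listed at 0 in telencephalon and at 156 FPKM in whole body. Of the 24 genes 6 rest on isoforms of 312 bases or less. A 204-base isoform carried 98.0% of Entpd1 in telencephalon (410 against 5.43 FPKM), and without isoforms under 300 bases its log2 ratio was 0.55 in place of 6.0. Trav13n-2 (264 bases) and RP24-72P6.1 (312) were listed at 0 in whole body. RP23-174P13.1 (142), RP24-116C1.6 (164) and RP23-380A10.6 (129) were listed at 0 in telencephalon.

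Long non-coding RNA genes, the class named by the study's design, were higher and lower in telencephalon in similar numbers. Of 662 measured genes 98 were at least 2-fold higher in telencephalon and 106 at least 2-fold lower, with 13 and 9 past 8-fold. By annotated class the counts were 38 higher and 37 lower among 212 intergenic genes, and 40 higher and 42 lower among 276 antisense genes, while 14 were higher and 24 lower among 138 processed transcripts. The library kit does not mark strand, so reads of an antisense gene and of the gene it overlaps cannot be told apart where their exons overlap. In 7 of the 98 higher and 6 of the 106 lower genes most of the signal in the higher library came from isoforms under 300 bases, as it did in 4 of the 13 and 4 of the 9 past 8-fold. Both counts vary with the pseudocount, the floor and the scaling, from 39 to 207 genes higher and 31 to 206 lower.

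The 6 long non-coding RNAs highest in telencephalon relative to whole body included Xist (chromosome X, 103460366 to 103483254) and Dlx6os1 (chromosome 6, 6820189 to 6871592), which lies opposite Dlx6 in the distal-less cluster of the ventral forebrain. The labels do not give the sex of the fetuses, so the difference in Xist may reflect sex and not tissue. Dlx6os1 stood at 32.9 against 0.807 FPKM. The 4 others chosen by size were listed at 0 in whole body, namely Gm11635 at 40.2 FPKM in telencephalon, Gm29587 at 13.6, Gm29044 at 10.9 and RP23-320I7.3 at 10.7. Of these Gm29587 has an annotated transcript of 332 bases, less than the 337 bases subtracted from lengths in telencephalon. In the other 3 the signal came from isoforms under 300 bases. At the lower end H19 (chromosome 7, 142575529 to 142578143) was 55.4-fold lower, C130021I20Rik 38.8-fold (0.343 against 13.3 FPKM) and Gm20412 31.0-fold (0.888 against 27.5). Tbx3os1, Gm10421 and RP24-388D8.6 completed that end, with isoforms of 282, 132 and 274 bases carrying 98.5%, 99.9% and 100% of their whole-body FPKM. Without isoforms under 300 bases, the log2 ratio of Tbx3os1 was -0.91 in place of -6.14 and that of Gm10421 was 1.47 in place of -4.94.

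Among the 30 measured genes of the list of known long non-coding RNAs, 8 were higher and 8 lower (median -0.56, mean -0.16, percentile 5.29). Besides Dlx6os1, the higher ones included Dlx1as (10.3 against 0.314 FPKM), Six3os1 (10.2 against 2.26), Pantr1 (114 against 19), which neighbours the brain transcription factor gene Pou3f3, and Miat (46.4 against 14.4). The lower ones included Airn, the imprinted RNA of the Igf2r locus (15.6-fold), Meg3 (78.7 against 232 FPKM) and Hoxa11os, listed at 0 in telencephalon and at 6.35 FPKM in whole body.

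Redrum (ENSMUSG00000096982), the RNA at the centre of the study and one known from red blood cell development, was lower in telencephalon. It is annotated as an intergenic RNA on the plus strand of chromosome 18, from 54422295 to 54453294 on GRCm38. Its 3 exons of 266, 107 and 1855 bases make a transcript of 2228 bases. It stood at 7.55 FPKM in whole body and 0.122 in telencephalon, 61.8-fold lower, with a log2 ratio of -2.93. This corresponds to about 423 and 5 fragments, whose ratio scaled by depth is 65.6 with a 95% exact interval from 27.9 to 203, covering counting error within these libraries only. Redrum ranked 12 from the lowest of the 662 long non-coding RNAs, and 18 of the 27 erythroid genes had lower ratios. The nearest measured coding gene on each side was within 2-fold. Zfp608, 434754 bases downstream, stood at 10.9 FPKM in telencephalon against 8.53, and Csnk1g3, 466747 bases upstream, at 12.8 against 10. Farther away, Gramd3, 1947043 bases downstream, was 7.80-fold lower in telencephalon (0.832 against 6.49 FPKM).

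**Figure D4:**
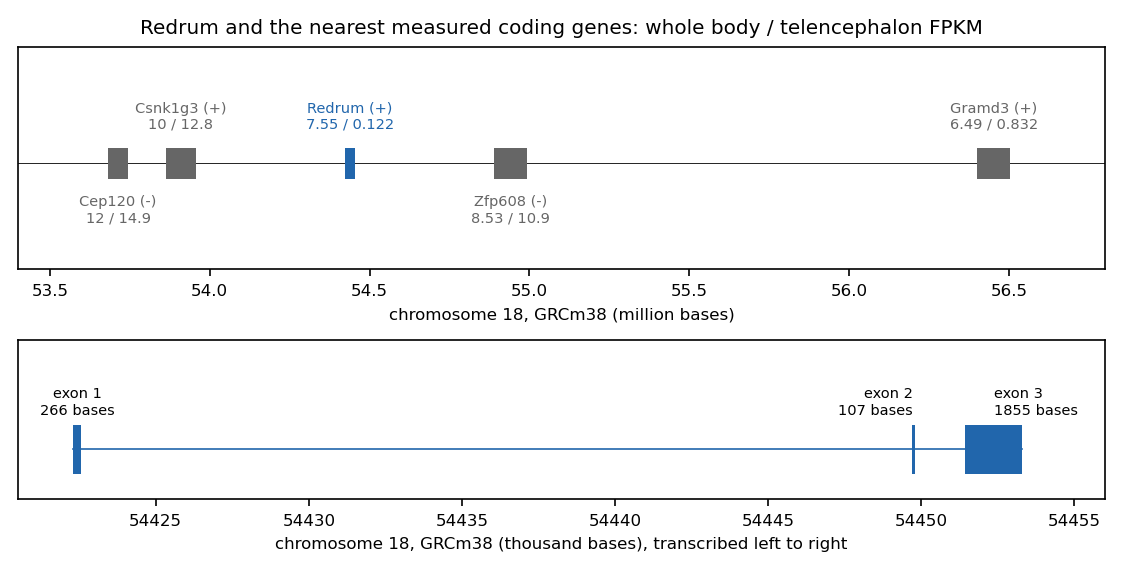
The upper panel maps Redrum and the nearest measured coding genes on chromosome 18 of GRCm38, with strand and FPKM in whole body and telencephalon, and the lower panel draws the 3 exons of Redrum to scale. Redrum stood at 7.55 against 0.122 FPKM, while Zfp608, Csnk1g3 and Cep120 were within 2-fold and Gramd3 was 7.80-fold lower.

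Isoform use was compared within 6326 genes that have at least 2 isoforms and summed FPKM of 5 or more in both libraries. In Rtn4rl2, a relative of the Nogo receptor, a 1303-base coding isoform made up 98.2% of the gene in telencephalon and 0.00247% in whole body, where one of 1263 bases held 97.9%. In Gng7, a G protein subunit gene, a 3382-base isoform made up 95.3% in whole body and 0.00332% in telencephalon, where one of 3362 bases held 91.4%. Katna1, a microtubule-severing enzyme, had a 1775-base isoform at 93.6% in whole body and 5.75% in telencephalon, where one of 1774 bases held 80%. In these 3 genes the leading isoforms of the 2 libraries are close in length. In Prom1, a membrane protein of progenitor cells, a 3664-base isoform made up 80.5% in whole body and was close to 0 in telencephalon, where a 3966-base isoform held 56.9%. In Entpd1 and Foxn3 the isoforms concerned were of 204 and 168 bases, and without isoforms under 300 bases the log2 ratio of Foxn3 as a gene was 1.70 in place of -1.62, resting on a 387-base isoform that held 71.5% of the gene in telencephalon. The most abundant isoform differed in 918 genes (14.5%), and 71 genes had an isoform whose share differed by 50 percentage points or more, 10 of them on an isoform under 300 bases. With a share of 60% or more asked of the leading isoform in each library, 3559 genes remained and 56 of them differed (1.57%). Cufflinks divides reads among overlapping isoforms by a model, and the shares are given here without an error.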

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

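The alternative without isoforms under 300 bases was chosen after the data were seen. No list median of 1 or more in size changed sign under any alternative, while that of Cajal-Retzius cells (-0.02) did. With 1 library per group there was no replicate to leave out, and depth limits the folds of genes with fewer than 10 fragments in telencephalon. No paired analysis was possible because each group has a single library. For the counts and medians below, the cause was not tested, except that a larger pseudocount shrinks and a smaller one widens the ratios of weak genes by construction.

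With a pseudocount of 5 FPKM, 800 genes were higher and 1490 lower, and 39 and 31 long non-coding RNAs. List medians were then -1.02 for Hox genes, -1.22 cardiac muscle, -1.40 skeletal muscle, -3.30 cartilage, bone and connective tissue, -0.51 diencephalon and eye, 1.47 pallium, 2.24 subpallium, -1.48 epithelia, -2.78 erythroid cells, -2.53 hepatoblasts, -0.72 hindbrain and periphery, -1.14 macrophages and -1.36 meninges. Members at least 2-fold lower then numbered 18 of 33 for Hox genes and 7 of 18 for hindbrain and periphery. Cardiac muscle had 12 of 19, macrophages 10 of 18, and skeletal muscle and epithelia 12 of 18 each. Cartilage had 23 of 25, erythroid cells 22 of 27 and hepatoblasts 21 of 24. With a pseudocount of 0.1 FPKM, 162 long non-coding RNAs were higher and 162 lower. List medians were -4.94 for Hox genes, -5.10 cardiac muscle, -5.73 skeletal muscle, -6.99 cartilage, -2.59 diencephalon and eye, -5.56 epithelia, -4.69 erythroid cells, -7.16 hepatoblasts and -3.87 hindbrain and periphery.

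With a floor of 5 FPKM, 2065 genes were lower, and 54 long non-coding RNAs were higher and 46 lower. The medians were -4.14 for cardiac muscle, -4.30 skeletal muscle, -3.34 diencephalon and eye, -5.50 hepatoblasts and -2.62 hindbrain and periphery, since fewer genes entered. In TPM 2126 genes were higher, and 202 long non-coding RNAs higher and 166 lower, with medians of -5.68 for cartilage, -5.56 hepatoblasts and -3.97 skeletal muscle. Without globin, mitochondrial and small RNA genes in the total, 207 long non-coding RNAs were higher and 206 lower, and the medians were -3.24 for Hox genes, -3.60 cardiac muscle, -4.23 skeletal muscle, -5.87 cartilage, -3.81 epithelia, -4.91 erythroid cells, -5.85 hepatoblasts and -2.74 hindbrain and periphery. The share of higher genes among all 2-fold differences moved less, from 30.8% as deposited to 37.2% in TPM and 39.6% with a common upper quartile.

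Genes with a different leading isoform numbered 1466 at a floor of 1 FPKM, 598 at 10 FPKM and 56 with a leading share of 60% or more. Those with a share difference of 50 points or more numbered 240 and 37 at the former floors. Among named genes Foxn3 (1.70 in place of -1.62) and Gm10421 (1.47 in place of -4.94) reversed without isoforms under 300 bases, which by construction removes their main isoform in whole body. Of the other recomputed ratios of named genes, 163 moved by 1.5 times or more, 102 of them with another pseudocount, and 666 did not.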

Other observations

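The gene families, the short-transcript pattern, and the tests on sex mixture, carry-over and blood were chosen after the values were seen. The tests on fetuses of a single sex, globin paralogs and neighbouring genes were set before their results.

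Several gene families were lower in telencephalon in most of their members, some of which also belong to the fixed lists. Collagen chains were lower in telencephalon in 34 of 36 measured genes (median log2 ratio -3.45, or -2.74 for the 28 outside the fixed lists), laminin chains in 9 of 10 (-2.06), integrin subunits in 17 of 21 (-1.64) and bone morphogenetic proteins in 7 of 7 (-1.99, or -1.93 for the 6 outside the lists). Integrin Itgb8, which acts in radial glia, was the 1 integrin at least 2-fold higher, with 8.19 against 2.26 FPKM. Among 14 Wnt ligands, 2 of them in the lists, 11 were lower (median -1.40), while Wnt7a (28.9 against 2.02 FPKM) and Wnt7b (62.3 against 13.9), both expressed by the embryonic brain, were higher. Of 9 GABA-A receptor subunits 5 were higher, among them Gabra2 (8.16 against 1.58 FPKM), and 1 lower, Gabrp (median 1.25). Of 15 ionotropic glutamate receptor subunits 5 were higher, none lower and 10 within 2-fold (median 0.75), with the higher ones including Grik3 (44.4 against 4.92) and Gria1 (23.0 against 3.14). The 79 ribosomal protein genes had a median of -0.72, with 17 lower and 1 higher. The 7 mitochondrially encoded genes had a median of -0.40 with none past 2-fold, and the 288 numbered zinc finger genes one of 0.13 with 11 higher and 7 lower. The signs of these medians were the same under each scaling tried.

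Y-linked genes and Xist differed between the libraries. Tissue differences in fetuses of a single sex would move Ddx3y, Uty, Kdm5d and Eif2s3y as their X-linked counterparts, yet all 4 were lower than these, by a median log2 difference of -2.05. Carry-over of whole-body RNA into a female sample is argued against by the smallest ratio of telencephalon to whole body among them, 18% for Ddx3y, which lies far above those of Alb (0.145%) and Afp (0.122%). What stays open is that fetuses of both sexes gave the telencephalon library and males the whole-body library, since Uty, the lowest of the 4, still had 1.81 FPKM in telencephalon while Xist had 0.0703 FPKM in whole body. If so, sex and tissue may differ together, which a further library of known sex would settle.

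Embryonic globins differed less between the libraries than the other erythroid genes except Bpgm (96.1% of whole body). Reads shared between paralogs are argued against, since 100% of the 50-base stretches of Hbb-y and of Hba-x transcripts occur in no other gene's transcripts. Carry-over of whole-body RNA would bring Alb at the same ratio, but the smallest embryonic globin ratio was 53.3% and that of Alb 0.145%. Blood with the erythroid makeup of the whole body would give erythroid genes similar ratios, which the pattern itself goes against. The 5 abundant erythroid genes other than globins had a median ratio of 2.59%, among them Slc4a1 (5.32 against 318 FPKM) and Alas2 (11.9 against 188). These 5 genes are part of the pattern, so their median restates it and is not a separate test. A hypothesis left untested is that circulating red cells of the yolk sac lineage, rich in embryonic globin, reached both samples while the precursors of the fetal liver reached the whole body alone, which libraries of sorted red cells would settle.

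In 30 genes the value was 0 in one library and 100 FPKM or more in the other. Of the 26 with a known length 25 have no transcript of 300 bases or more (96.2%), against 0.731% of all measured genes with a length, and the exception was Apoa2. Lower depth of the telencephalon library is argued against as the only cause, since 60% of the 30 were at 0 there and 12 were at 0 in whole body. With a relative depth of only 1.29, these shares cannot exclude a contribution of depth. An unstable length correction for transcripts shorter than the fragments is a candidate explanation, and a biological difference was not tested. The same limit applies to 6 of the 12 long non-coding RNAs chosen by size, whose signal came from isoforms under 300 bases. Gm29587, with 332 bases, is also shorter than the 337 bases subtracted from lengths in telencephalon.

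Long non-coding RNA genes varied with the nearest protein-coding gene. The hypothesis was that the 2 genes of a pair share tissue specificity beyond chance. Among 258 pairs that do not overlap, Spearman's rho of the log2 ratios was 0.42, and the central 95% of 10000 re-pairings ran from -0.12 to 0.12. The coefficient was 0.62 in 388 overlapping pairs, where reads can be counted for both genes, and 0.29 in 120 pairs more than 10000 bases apart, which 9 of the re-pairings reached. Examples chosen after the values were seen are Pantr1 (2.52) beside Pou3f3 (2.66), 926 bases apart, Gm14204 (3.51) beside the GABA transporter gene Slc32a1 (2.81), 44 bases apart, and Hoxa11os (-2.88) beside Hoxa10 (-3.01). Redrum (-2.93) with Zfp608 (0.31) went the other way. Unannotated ends of the coding gene, which could extend into a close neighbour, were not tested, and the pairs are not independent.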
